A study of Rattus norvegicus with 17 samples.

How the data were processed

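Gene expression was measured by sequencing polyA-selected RNA of fetal testes from Sprague Dawley rats, in 17 libraries. Per the labels' protocols, pregnant dams received dipentyl phthalate (DPeP), a plasticizer of the phthalate ester class, or the corn oil vehicle by oral gavage in 2.5 mL/kg from gestational day 17 to 21, and testes were taken on gestational day 21. Each library held RNA of 1 testis or of 2 pooled testes of the same litter. Whether every library came from its own dam is not given in the sources used here. Libraries were made with the NEBNext Ultra II RNA kit, which does not mark strand, so genes that overlap another gene or have an antisense partner carry uncertain counts.

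Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to the build mRatBN7.2 and assigned to genes with featureCounts of Subread 1.5.2. The notes name DESeq2 and limma as well, without their role. The deposited count files give, per the file headers, the raw read count of each gene with its coordinates and its summed exon length in bases. The release of the gene models and the strand setting of the counting are not given in the sources used here. A deposited table for the whole series held the same counts with rows repeated for many genes, 47125 rows for 30652 identifiers, and no count differed from the files per library. A second deposited table held TPM (counts over gene length, scaled to the same total) computed by the authors, here treated as a score because its repeated rows make its columns sum to more than TPM allow. Once each gene was kept 1 time, these values differed from counts over length by at most 5e-05. A deposited table of log2 values of the same counts was not analysed here.

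All values below were computed from the deposited counts. The 92 rows of ERCC spike-in RNA were left out, which left 30560 genes, 24044 of them named in the deposited tables and 6516 with no symbol. The spike-in rows were not used for scaling, because their input amounts are not given in the sources used here. Fold changes are therefore relative to the total RNA of genes in each library. Coordinates are those of the count files. Levels are CPM (gene counts scaled to the same total in each library) with TMM-scaled library sizes, and log2 CPM used a prior count of 2.

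Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. TMM normalization, filterByExpr by dose group and 1 fit of all 17 libraries were used, which tested 18005 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in its comparison. Each dose was compared with vehicle, 300 with 100 mg/kg/d, and 1 slope on log2(dose + 1) was fitted over all libraries. Standard errors are the size of the log2 fold change over the square root of its F value. The choice of the main tests, gene lists and named genes was made before the data were examined.

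The 19 gene lists held 354 entries, of which 340 matched a gene and 328 were tested. They covered androgen synthesis, cholesterol uptake and transport, cholesterol synthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, oxidative stress, p53 targets and cell death, cell cycle and immediate early genes. They also covered markers of Leydig, Sertoli, germ, peritubular myoid, interstitial fibroblast, endothelial, macrophage and red blood cells, of mesonephric duct and epididymis and of adrenal cortex. Some genes stand in several lists, such as Star and Cyp11a1 in the androgen synthesis and Leydig cell lists. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, with adjustment over the 19 lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Counts of list members are given over all genes and, where stated, adjusted over the list alone.

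The named genes follow a rule with 3 parts. A panel of 12 genes was given at every dose. From each list, up to 4 called members with the smallest adjusted p were named, or the 2 members with the highest mean CPM where none was called. In each comparison, the 8 highest and 8 lowest log2 fold changes were named among called genes with a mean CPM of at least 1, a gene symbol and no overlap between the groups. A comparison with 16 or fewer called genes names all that have a symbol. Not every gene that the rule selects is described in the text.

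The tests were run on simulated counts with 200 changed genes, drawn from the vehicle means, the dispersions of the genes and the sizes of these libraries. The changed genes were chosen among those with a vehicle mean of at least 1 CPM, 66 or 67 per fold change, and the draw was not repeated. Each gene had 1 dispersion for all groups, so a wider spread among the libraries at 100 mg/kg/d was not simulated. For 300 mg/kg/d against vehicle, 50.7% of genes changed by 1.5-fold, 86.6% changed by 2-fold and 98.5% changed by 4-fold were recovered among 17564 genes. The shares for 100 mg/kg/d against vehicle were 37.3%, 70.1% and 98.5% among 17557 genes. For 11 mg/kg/d they were 37.3%, 83.6% and 97.0% among 17556 genes, and for 1 mg/kg/d 34.3%, 82.1% and 97.0% among 17568 genes. False calls made up 3.68%, 6.80%, 3.97% and 5.96% of the calls at 300, 100, 11 and 1 mg/kg/d, so at 100 and 1 mg/kg/d they were above the 0.05 set for calling. No 2 libraries of a group were duplicates, as the 22 pairs of libraries within groups had a chi-square per degree of freedom of 6.83 to 84.5.

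The titles carry a sample code with 3 values, each with 1 vehicle library, whose meaning is not given in the sources used here. It was tested as a covariate, since each code spans more than 1 group. The code of vehicle replicate 08 holds only libraries of vehicle and 1 mg/kg/d. Other alternatives were median-of-ratios size factors, no low-count filter, and a filter of 1 CPM in at least 3 libraries. DESeq2 1.42.0, limma-voom and limma on the log2 of the deposited TPM with a pseudocount of 1 or 0.1 were run as other tests. DESeq2 took every gene with at least 1 count, 26779 genes between groups against 18005 in edgeR, so its counts of calls differ in gene set as well as in method. Fits of only the groups compared, fits without each library in turn, subsets of 3 libraries of the 300 mg/kg/d group and slopes on the dose or its rank were run as well. Removal of each library's trend of expression on gene length, and fits without replicates 05 and 18 of the 100 mg/kg/d group, were added after seeing the data. Replicate numbers do not repeat over the libraries, so no paired analysis was possible. Gene content of G and C was not checked, because no genome sequence of the build was at hand, and neither was the sharing of reads between related genes such as those of the Gsta and Hsd3b families.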

Results

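The study measured gene expression in the testes of rat fetuses whose dams received DPeP by gavage from gestational day 17 to 21. The 17 libraries fell into 5 groups: corn oil vehicle (n = 3), 1 mg/kg/d (n = 3), 11 mg/kg/d (n = 3), 100 mg/kg/d (n = 3) and 300 mg/kg/d (n = 5). The vehicle libraries held 15948971, 17920695 and 16398867 gene counts in replicates 01, 08 and 15. At 1 mg/kg/d, replicates 02, 09 and 10 held 15661373, 14282274 and 15777640, and at 11 mg/kg/d replicates 03, 16 and 17 held 16441873, 17931220 and 18755376. Replicates 05, 18 and 19 at 100 mg/kg/d held 17551414, 20323488 and 14781634. Replicates 06, 07, 13, 14 and 20 at 300 mg/kg/d held 16498780, 17409433, 17261328, 17095796 and 17345895. Between 21466 and 22529 genes had a count in each library. Levels are given as CPM with SD, and the adjusted p values are those of edgeR's quasi-likelihood test.

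Replicates 05 and 18 at 100 mg/kg/d stood apart from the other 15 libraries in several measures. Genes of the mitochondrial genome took 9.05% and 7.76% of their gene counts, against 4.35% to 6.16% in the other libraries, and 5.26% in replicate 19 of the same dose. Genes of ribosomal proteins took 6.96% and 6.28% of their counts, against a vehicle mean of 4.67% ± 0.421 (SD, n = 3). Their correlation of expression with log2 gene length was -0.29 and -0.20 across genes, which are not independent replicates, against -0.13 to 0.16 in the other libraries, with the lowest of these in vehicle replicate 15.

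**Figure D1:**
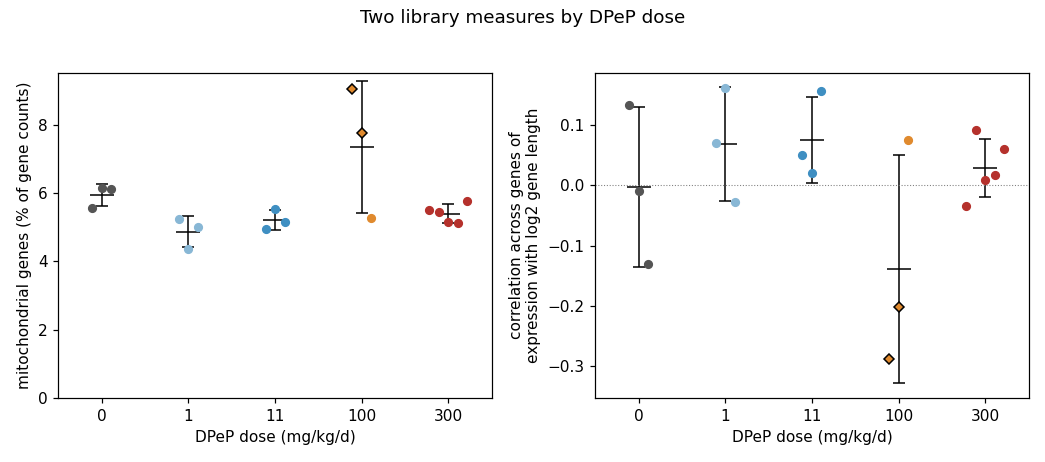
Left, share of gene counts from mitochondrial genes in percent; right, correlation across genes of expression with log2 gene length; both against the DPeP dose in mg/kg/d, where 0 is vehicle. Points are single libraries, diamonds are replicates 05 and 18 at 100 mg/kg/d, and bars give the mean and SD; these diamonds lie at 9.05% and 7.76% in the left plot and at -0.29 and -0.20 in the right plot.

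The comparison of 300 mg/kg/d with vehicle asked which testis genes differed at the highest dose. Several genes of steroid hormone synthesis in Leydig cells, the androgen-producing cells of the fetal testis, fell. Cyp17a1, an enzyme of androgen synthesis, dropped from 1504 ± 191 CPM (SD, n = 3) to 347 ± 83.4 CPM (SD, n = 5), 4.33-fold lower. Star, which carries cholesterol into mitochondria, was 4.27-fold lower, at 148 ± 41.1 CPM (SD, n = 5) against 632 ± 73.7 CPM (SD, n = 3). Insl3, a Leydig cell hormone of testis descent, was 5.13-fold lower, and Scarb1, a receptor that takes up cholesterol from lipoproteins, was 3.80-fold lower. Some genes of Sertoli cells, the supporting cells of the cords, rose, with 5 of 23 markers called. Among these, Amh was 1.78-fold higher, at 2534 ± 818 CPM (SD, n = 5) against 1421 ± 230 CPM (SD, n = 3).

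In all, 432 of 18005 genes were called at 300 mg/kg/d, of which 179 rose and 253 fell, and 104 of those that fell and 62 of those that rose did so by at least 2-fold. The log2 fold changes were -2.12 for Cyp17a1 (SE 0.178, adjusted p = 4.85e-07), -2.09 for Star (SE 0.181, adjusted p = 7.33e-07), -2.36 for Insl3 (SE 0.237, adjusted p = 3.86e-06) and -1.93 for Scarb1 (SE 0.169, adjusted p = 7.44e-07). Each was below every vehicle library in 5 of 5 libraries. Cyp11a1, which makes the first steroid from cholesterol, changed by -1.71 (SE 0.151, adjusted p = 7.44e-07) and Nr0b1, a nuclear receptor, by -0.96 (SE 0.128, adjusted p = 0.000118). Ensembl identifiers and positions on mRatBN7.2 were ENSRNOG00000020035 on chromosome 1, 245535462 to 245541573, for Cyp17a1, and ENSRNOG00000015052 on chromosome 16, 66264807 to 66271672, for Star. Insl3 is ENSRNOG00000068505 on chromosome 16, 18384829 to 18400560, and Scarb1 is ENSRNOG00000000981 on chromosome 12, 31296156 to 31362647. Cyp11a1 is ENSRNOG00000008074 on chromosome 8, 58404669 to 58434338. Not every steroid gene was called: Hsd17b3 had a log2 fold change of 0.25 (SE 0.156, adjusted p = 0.541).

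Within the sample code of vehicle replicate 15, the log2 ratio to vehicle was -2.20 for Cyp17a1, -2.25 for Star, -2.49 for Insl3 and 1.00 for Amh, over 2 libraries at 300 mg/kg/d and 1 vehicle library. Within the code of vehicle replicate 01, with 3 such libraries, the ratios were -2.23, -1.87, -2.34 and 0.49. The code of vehicle replicate 08 held no library of this dose.

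**Figure D2:**
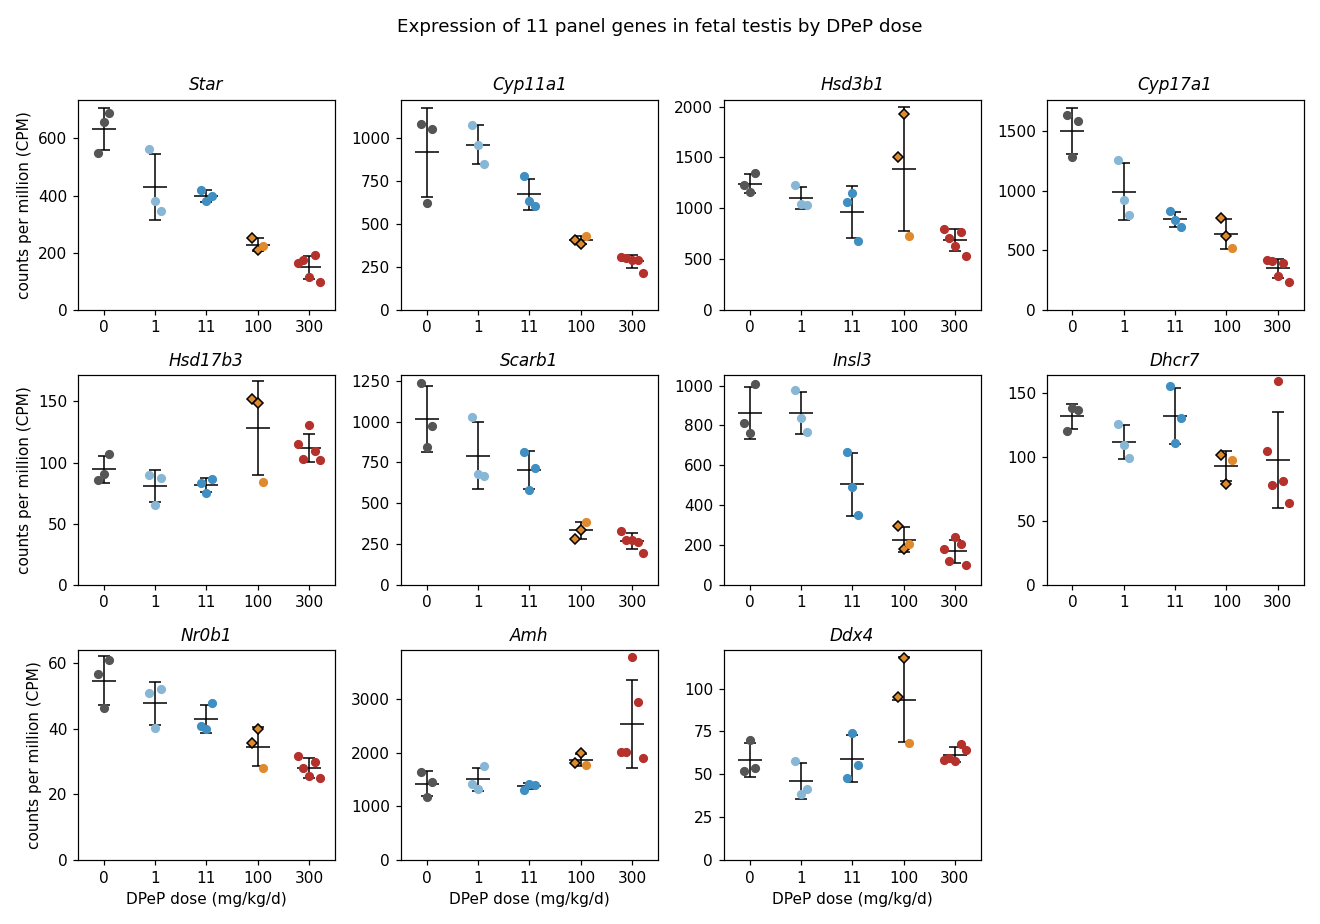
Expression in CPM (vertical axes, from 0) of 11 genes against the DPeP dose in mg/kg/d, where 0 is vehicle. Points are single libraries, diamonds are replicates 05 and 18 at 100 mg/kg/d, and bars give the mean and SD; Star falls from a vehicle mean of 632 CPM to 148 CPM at 300 mg/kg/d, and Hsd3b1 has a mean of 1387 CPM with an SD of 609 at 100 mg/kg/d.

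Of the 14 tested androgen synthesis genes, 9 fell at 300 mg/kg/d and none rose, and 9 fell and 1 rose adjusted over the list alone. Fdx1, which passes electrons to steroid enzymes of mitochondria, fell by 1.75 on the log2 scale (SE 0.172, adjusted p = 3.00e-06). The list's camera test gave an adjusted p of 7.77e-28, and adjusted p = 0.000294 with an estimated correlation. Of 22 Leydig cell markers, 11 fell and 1, Ptgds, rose, with 14 and 2 adjusted over the list alone; adjusted p was 3.47e-32, and 2.07e-05 with an estimated correlation. Hsd3b1, an enzyme of both lists whose reads were not checked for sharing with related genes, fell by 0.86 (SE 0.215, adjusted p = 0.0368), from 1241 ± 95.2 CPM (SD, n = 3) to 685 ± 105 CPM (SD, n = 5). Its adjusted p ranged from 0.000209 to 0.175 over 19 alternatives. The adrenal cortex list had 3 tested members, 2 of which fell, and 2 fell and 1 rose adjusted over the list alone. Mrap, a partner of a hormone receptor of the adrenal cortex, had a log2 fold change of -3.32 (SE 0.190, adjusted p = 3.23e-09). Cyp11b1, an enzyme of corticosterone synthesis, had -4.35 (SE 0.384, adjusted p = 7.44e-07). The adrenal cortex list had an adjusted p of 1.31e-20 by camera, and 9.08e-05 with an estimated correlation.

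Cholesterol synthesis fell as a list, with 11 of 22 members down and none up, and 13 down and 1 up adjusted over the list alone. Tm7sf2 fell by 1.30 (SE 0.227, adjusted p = 0.00209), Msmo1 by 1.00 (SE 0.160) and Hmgcs1, an early enzyme of the pathway, by 0.92 (SE 0.140). Camera gave an adjusted p of 1.31e-20, and 0.0129 with an estimated correlation. Dhcr7, an enzyme of the last step, had a log2 fold change of -0.44 (adjusted p = 0.345). Of 18 genes of cholesterol uptake and transport, 3 fell, among them Scarb1 and Plin2, and 1 rose (Abcg1, an exporter, by 0.87, SE 0.182), with adjusted p of 0.000544, and 0.0129 with an estimated correlation. In fatty acid synthesis 5 of 13 genes fell, Acss2 by 1.02 and Me1 by 0.81, with adjusted p of 0.000107, but 0.103 with an estimated correlation. In PPAR targets and fatty acid oxidation 3 of 25 fell, Fabp3 by 0.78, Vnn1 by 0.50 and Acadvl by 0.36, with adjusted p of 9.43e-05, but 0.0790 with an estimated correlation.

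Of 23 Sertoli cell markers, 5 rose and none fell, and 10 rose adjusted over the list alone. The log2 fold changes were 0.84 for Sox8 (SE 0.150, adjusted p = 0.00265), 0.84 for Clu (SE 0.151), 0.97 for Fgf9 (SE 0.199) and 0.83 for Amh (SE 0.187, adjusted p = 0.0180). The list had an adjusted p of 4.16e-07, and 0.0129 with an estimated correlation. The Amh call was lost without vehicle replicate 08 or 15 or replicate 14 at 300 mg/kg/d, and with the sample code in the fit, at adjusted p up to 0.118. Of 28 germ cell markers, 1 rose, Nanos2, by 1.48 (SE 0.388, adjusted p = 0.0465), and Ddx4 had a log2 fold change of 0.07 (SE 0.169, adjusted p = 0.908). The list had an adjusted p of 2.26e-05, but 0.129 with an estimated correlation.

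Cell cycle genes had lower values in 24 of 24 members; 1 fell over all genes, Rrm2, by 0.37 (SE 0.0980, adjusted p = 0.0476), and 9 fell adjusted over the list alone. Their adjusted p was 1.70e-10, and 0.0129 with an estimated correlation. In the mesonephric duct and epididymis list 1 of 10 members rose, Lcn2, a secreted lipid-binding protein, by 2.01 (SE 0.288, adjusted p = 0.000272), and the list had an adjusted p of 0.000120, and 0.0364 with an estimated correlation. Tyrobp was the 1 macrophage marker of 15 that fell, by 1.02 (list adjusted p = 0.0198, but 0.271 with an estimated correlation). Sod2 and Gclc were the 2 genes of 18 in the oxidative stress list that fell, by 0.73 and 0.54 (0.00284, but adjusted p = 0.129 with an estimated correlation). Nr4a1, an orphan nuclear receptor, was the 1 immediate early gene of 20 that rose, by 1.13 (list adjusted p = 0.0313, but 0.346 with an estimated correlation). Pmaip1, a promoter of cell death, rose by 1.11 as 1 of 18 genes of the p53 list, whose adjusted p was 0.749.

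No member of the myoid, fibroblast, endothelial or red blood cell lists was called at 300 mg/kg/d. The 12 myoid genes had a median log2 fold change of 0.30 (adjusted p = 0.000571, but 0.264 with an estimated correlation). The 13 endothelial genes had a median of -0.21 (0.00297, but adjusted p = 0.293 with an estimated correlation). The adjusted p was 0.446 for the 16 fibroblast genes and 0.584 for the 14 red blood cell genes.

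Falls and rises at 300 mg/kg/d were ranked among called genes with a mean CPM of at least 1, a gene symbol and no overlap between groups. The largest falls were those of Gsta2, Cyp11b1, Svs5, Gpr55, Fcer2, Cdh1, Mrap and Lefty2. Gsta2, a glutathione transferase whose reads were likewise not checked for sharing with related genes, went from 16.7 ± 7.93 CPM (SD, n = 3) to 0.162 ± 0.222 CPM (SD, n = 5). Svs5, a seminal vesicle secretory protein, went from 191 ± 71.5 to 10.4 ± 6.49 CPM and Lefty2, an inhibitor of Nodal signals, from 4.63 ± 0.413 to 0.559 ± 0.204 CPM. Cdh1, E-cadherin, went from 106 ± 44.5 to 10.0 ± 3.09 CPM (adjusted p = 0.0499), and libraries at 1 and 11 mg/kg/d were as low, at 2.98 to 6.43 CPM in 3 of 6. The 8 largest rises were those of Lcn2, Stc1, Sox10, Tmem221, Hrc, Slc34a2, Synpo2l and Ntn4. Stc1, a secreted glycoprotein, rose from 6.51 ± 1.11 to 25.6 ± 6.07 CPM and Sox10, a transcription factor, from 1.76 ± 0.486 to 6.99 ± 2.31 CPM. Of the 49 called genes named for this comparison, 30 were called in each alternative run; Cdh1 and Rrm2 lost their calls in 14 of 19, Nanos2 in 12 and Hsd3b1 in 10. The count of 432 fell to 256, 264 and 212 without vehicle replicates 01, 08 and 15, and was 270 with the sample code in the fit. It was higher in DESeq2, at 724, and in a fit of the compared groups alone, at 835.

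At 100 mg/kg/d 10 of 22 Leydig cell markers and 6 of 14 androgen synthesis genes also fell against vehicle. Mrap dropped from 13.9 ± 1.61 to 2.51 ± 0.281 CPM (SD, n = 3 each), 5.55-fold lower, and Insl3 from 862 ± 130 to 226 ± 62.6 CPM, 3.82-fold lower. Scarb1 was 3.05-fold lower, Star 2.77-fold lower, Cyp17a1 2.36-fold lower and Cyp11a1 2.26-fold lower, each below every vehicle library in 3 of 3 libraries. Lcn2 was 3.13-fold higher and Sox10 2.97-fold higher. The germ cell marker Dazl was 1.77-fold higher, at 45.7 ± 9.08 against 25.8 ± 2.82 CPM.

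In this comparison 274 genes were called, 89 up and 185 down, with replicates 05 and 18 in the fit. Without both of these libraries 73 were called, 13 up and 60 down, where replicate 19 is assumed to vary like the other groups. The log2 fold changes were -2.47 for Mrap (SE 0.214, adjusted p = 4.16e-06), -2.87 for Olfm2 (SE 0.254, adjusted p = 4.16e-06) and -5.31 for Gsta2 (SE 0.505, adjusted p = 7.12e-06). They were -1.93 for Insl3 (SE 0.278, adjusted p = 0.000851), -1.47 for Star (SE 0.211, adjusted p = 0.000851), -1.61 for Scarb1 (SE 0.198, adjusted p = 0.000149) and -1.24 for Cyp17a1 (SE 0.205, adjusted p = 0.00280). These 7 genes were called in each of 17 alternatives, as was Cyp11b1, with a highest adjusted p of 0.0433 for Star. Within the code of vehicle replicate 15, with 2 libraries at this dose, the log2 ratio to vehicle was -2.02 for Insl3, -1.54 for Star and -1.30 for Cyp17a1. Within the code of vehicle replicate 01, with 1 library at this dose, the ratios were -2.19, -1.39 and -1.41, and the code of vehicle replicate 08 held none.

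Of 22 Leydig cell markers, 10 fell at 100 mg/kg/d and none rose, with 13 down and 2 up adjusted over the list alone. Lhcgr, the receptor of luteinizing hormone, fell by 1.67 (SE 0.243, adjusted p = 0.000935). The list's camera test gave an adjusted p of 1.64e-14, and 0.00174 with an estimated correlation. Of 14 androgen synthesis genes 6 fell, Fdxr by 0.86 (SE 0.131, adjusted p = 0.00154), and 7 fell and 1 rose adjusted over the list alone. In all 8 had lower and 6 higher values, with a list adjusted p of 1.37e-07, and 0.0460 with an estimated correlation. Hsd3b1 had a log2 fold change of 0.16 (SE 0.244, adjusted p = 0.740), with 1507 and 1926 CPM in replicates 05 and 18 and 726 CPM in replicate 19. Of 18 genes of cholesterol uptake 2 fell, among them Scarb1, with a list adjusted p of 5.10e-05, and 0.00934 with an estimated correlation. Of 3 adrenal cortex genes 2 fell, Mrap and Cyp11b1, and 2 fell and 1 rose adjusted over the list alone. The adrenal cortex list had an adjusted p of 4.58e-07, and 0.00934 with an estimated correlation.

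In cholesterol synthesis 1 of 22 genes fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone. That list had an adjusted p of 1.18e-06, but 0.136 with an estimated correlation. In fatty acid synthesis 4 of 13 genes fell, Acss2 by 0.71 and Elovl5 by 0.49, with adjusted p of 4.58e-07, but 0.0544 with an estimated correlation. In the cell cycle list 3 of 24 fell, Aurka by 0.47, Rrm2 by 0.47 and Plk1 by 0.44, with adjusted p of 1.12e-06, but 0.0544 with an estimated correlation.

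Few markers of other cells were called at 100 mg/kg/d, where replicates 05 and 18 had the mitochondrial shares of 9.05% and 7.76%. Of 28 germ cell markers 2 rose, Dazl by 0.82 (SE 0.161, adjusted p = 0.0109) and Sycp3 by 0.82 (SE 0.205, adjusted p = 0.0472), and 17 rose adjusted over the list alone. Of 13 endothelial markers 1 fell, Cdh5, by 0.84 (SE 0.185, adjusted p = 0.0238), and 8 fell adjusted over the list alone. The adjusted p was 4.89e-09 for the germ cell list, but 0.0544 with an estimated correlation, and 1.57e-07 for the endothelial list, but 0.0846 with an estimated correlation. A germ cell minus endothelial score, set to a mean of 0 in vehicle, was 1.21 and 1.20 in replicates 05 and 18, 0.51 in replicate 19 and at most 0.63 in the 300 mg/kg/d libraries. The Dazl call was lost without replicate 05 or 18 or vehicle replicate 01, and the Sycp3 call without any 1 of vehicle replicates 01, 08 and 15 and replicates 05 and 18. Over all 17 alternatives the adjusted p reached 0.280 for Dazl and 0.900 for Sycp3.

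The 10 genes of the mesonephric duct and epididymis list had higher values, with 1 called, Lcn2 (adjusted p = 0.000707 for the list, but 0.0643 with an estimated correlation). The red blood cell list, with none of 14 called, had an adjusted p of 0.00526, but 0.455 with an estimated correlation. The fibroblast list, with none of 16 called, had 0.00526, but adjusted p = 0.136 with an estimated correlation, and the PPAR list, with none of 25 called, had 0.00125, but adjusted p = 0.136 with an estimated correlation. Pmaip1 rose by 0.77 as 1 of 18 genes of the p53 list, whose adjusted p was 0.846. The Sertoli, myoid, macrophage, immediate early and oxidative stress lists had no called member, and adjusted p of 0.239, 0.232, 0.846, 0.642 and 0.459. The count of 274 was 94 without vehicle replicate 01, 99 without vehicle replicate 15, 162 without replicate 05, 93 without replicate 18 and 4250 without replicate 19. In limma on log2(TPM + 1) it was 191, of which 25 rose and 166 fell, with a median of all genes at -0.06 against 0.05 for edgeR.

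**Figure D3:**
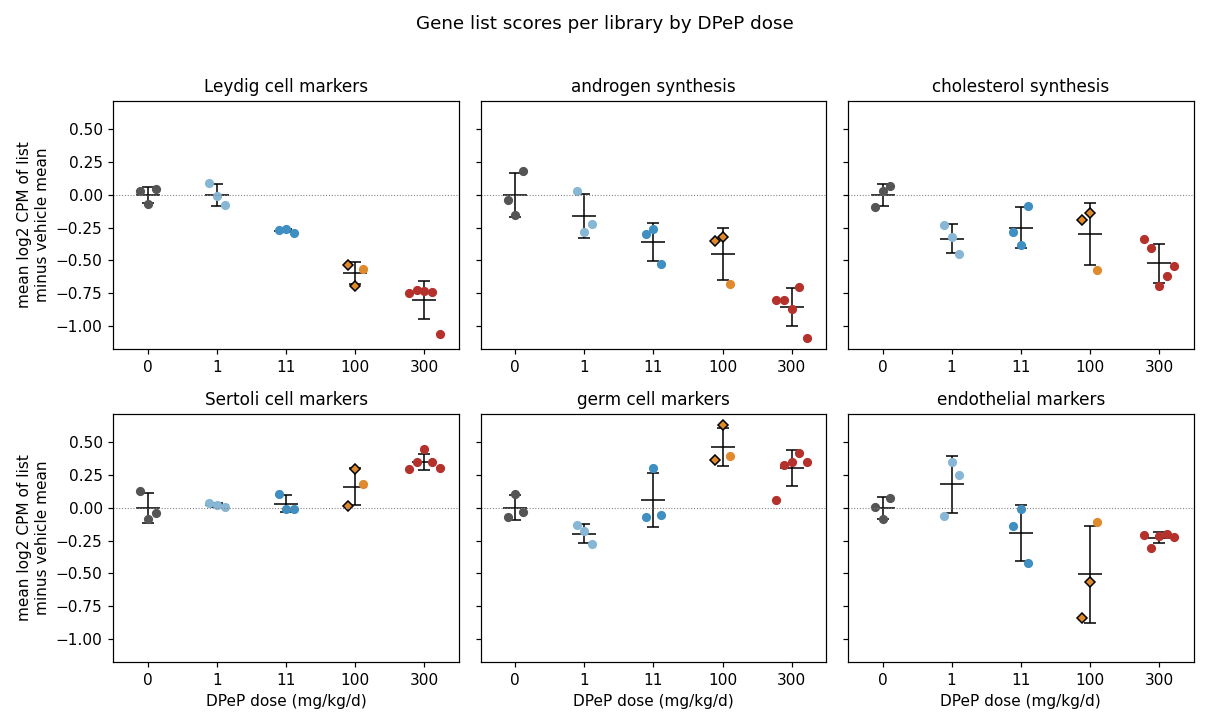
Mean log2 CPM of the tested genes of 6 lists minus the vehicle mean (vertical axes) against the DPeP dose in mg/kg/d, where 0 is vehicle. Points are single libraries, diamonds are replicates 05 and 18 at 100 mg/kg/d, and bars give the mean and SD; the Leydig cell score of the 300 mg/kg/d libraries lies between -0.75 and -0.73 in 4 of 5 and at -1.06 in replicate 20.

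The comparison of 300 with 100 mg/kg/d tested the difference between the highest doses itself. Cpe, carboxypeptidase E, which trims peptide hormones, was the 1 called gene, 2.13-fold higher at 300 mg/kg/d, with 33.7 ± 3.53 CPM (SD, n = 5) against 15.8 ± 2.75 CPM (SD, n = 3). Its level was 29.0 to 37.5 CPM in the libraries at 300 mg/kg/d and 10.3 to 18.9 CPM in the other 12 libraries. The log2 fold change was 1.09 (SE 0.154, adjusted p = 0.0143), on chromosome 16, 25030276 to 25142233 (ENSRNOG00000043387). Cyp17a1 and Hsd3b1 had log2 fold changes of -0.87 (SE 0.178) and -1.02 (SE 0.214), each at adjusted p = 0.0837, and Insl3 -0.42 (SE 0.239, adjusted p = 0.277).

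Without an adjusted threshold, 4362 of 18005 genes had p under 0.05 in this comparison. DESeq2, which took 26779 genes without the low-count filter, called 1244, and edgeR without that filter called 225. The count of 4362 depended strongly on single libraries at 100 mg/kg/d. It was 1385 without replicate 05, 2855 without replicate 18 and 7607 without replicate 19. The Cpe call was lost in 7 of 20 alternatives, at adjusted p up to 0.162. These were the fits without replicate 05, without replicates 05 and 18, without replicate 14 or 20 at 300 mg/kg/d, with the sample code, with the compared groups alone and with 3 libraries at 300 mg/kg/d; without replicate 19, 5872 genes were called. Of the 19 lists 12 were called by camera, 5 up and 7 down, among them the myoid genes up (adjusted p = 3.55e-05) and androgen synthesis down (adjusted p = 0.000288). None of the 12 was called with an estimated correlation, where these adjusted p values were 0.380 and 0.244.

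At 11 mg/kg/d no gene was called against vehicle by edgeR. In that fit of all libraries 633 of 18005 genes had p under 0.05 before adjustment, fewer than the share of 0.05 that chance gives. With the compared groups alone 1067 of 16944 did, more than that share, and 10 were called. Mrap had a log2 fold change of -1.16 (SE 0.197, adjusted p = 0.0604), with 6.24 ± 0.571 against 13.9 ± 1.61 CPM (SD, n = 3 each). Cyp17a1 had -0.99 (SE 0.204, adjusted p = 0.136), Insl3 -0.78 (SE 0.270), Star -0.66 (SE 0.207) and Scarb1 -0.53 (SE 0.193), the last 3 at adjusted p of 0.947 to 0.992. These 5 genes were below every vehicle library in 3 of 3 libraries. As groups, 3 lists were called down by camera also with an estimated correlation: Leydig cell markers (9.56e-08, and adjusted p = 0.0152 with an estimated correlation), androgen synthesis (3.00e-09, and adjusted p = 0.0274 with an estimated correlation) and the 3 adrenal cortex genes (2.65e-07, and adjusted p = 0.0152 with an estimated correlation). By fry the androgen synthesis list was not called (adjusted p = 0.0773), while the Leydig cell and adrenal cortex lists were (adjusted p = 0.0486 each). Of 22 Leydig cell markers 17 had lower values, and 5 fell adjusted over the list alone.

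The 6 other lists called at 11 mg/kg/d lost their calls with an estimated correlation. They were cholesterol synthesis (adjusted p = 0.134 with an estimated correlation), red blood cells (0.134), oxidative stress (0.134), macrophages (0.318), endothelial cells (0.405) and, upward, myoid cells (0.405). DESeq2 called 24 genes, limma-voom 2, limma on log2(TPM + 1) 1, and edgeR 2 without vehicle replicate 08.

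At 1 mg/kg/d no gene was called by edgeR, DESeq2 or limma-voom. In the edgeR fit of all libraries 891 of 18005 had p under 0.05 before adjustment, no more than the share of 0.05 that chance gives. The smallest adjusted p was 0.864. With the compared groups alone 1471 of 16771 had p under 0.05, more than that share, and 3 were called. Hmgcs1, an early enzyme of cholesterol synthesis, had 210 ± 13.5 CPM (SD, n = 3) against 319 ± 46.7 CPM in vehicle (SD, n = 3), a log2 fold change of -0.60 (SE 0.160). Cyp17a1 had a log2 fold change of -0.60 (SE 0.203), Star -0.56 (SE 0.207), Insl3 0.00 (SE 0.268) and Col1a1 0.51 (SE 0.159). Of 22 cholesterol synthesis genes 19 had lower values and 6 fell adjusted over the list alone; camera gave an adjusted p of 1.43e-12, but 0.280 with an estimated correlation. Camera called 8 lists, 3 up and 5 down, and 0 with an estimated correlation.

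Over all 17 libraries, the slope on log2(dose + 1) was called for 1030 genes, of which 494 rose and 536 fell with dose. Leydig cell and steroid genes were among those that fell. Relative to the vehicle mean, Star stood at 68.0%, 63.1%, 36.1% and 23.4% at 1, 11, 100 and 300 mg/kg/d, Cyp17a1 at 66.1%, 50.5%, 42.3% and 23.1%, and Insl3 at 99.9%, 58.4%, 26.2% and 19.5%. Slopes per unit of log2(dose + 1) were -0.23 for Star (SE 0.0217, adjusted p = 3.34e-07), -0.22 for Cyp17a1 (SE 0.0228, adjusted p = 1.75e-06), -0.31 for Insl3 (SE 0.0254, adjusted p = 6.51e-08) and 0.10 for Amh (SE 0.0203, adjusted p = 0.00491). Hsd3b1, Hsd17b3, Dhcr7 and Ddx4 were not called for a slope, at adjusted p of 0.294, 0.0745, 0.182 and 0.217. Without replicates 05 and 18 at 100 mg/kg/d 1711 genes were called, with the sample code in the fit 586 and with the slope on the dose itself 583.

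The calls at 100 and 300 mg/kg/d shared 144 genes in the same direction, 23 that rose and 121 that fell, and none in opposite directions. Star, Cyp17a1, Cyp11a1, Insl3, Scarb1, Nr0b1, Mrap, Cyp11b1 and Gsta2 were among those that fell at both doses, and Lcn2, Sox10 and Pmaip1 among those that rose. Over all genes 61.1% had the same sign at both doses, below the 68.9% of simulated unchanged groups that shared the vehicle libraries. Independent lists of these sizes would share 3.48 genes, a number that leaves out the vehicle libraries both comparisons share. The covariance of the log2 fold changes over all genes was 0.123, against a simulated mean of 0.0428, where the simulated groups shared the vehicle libraries as the real ones do. The simulation drew each gene independently, with 1 dispersion for all groups, so it lacked the wider spread at 100 mg/kg/d and any shared variation of genes between libraries. The excess in covariance therefore cannot be read as a shared response to dose. The shared count was 70 without vehicle replicate 01, 74 without vehicle replicate 15, 76 without replicate 18 and 301 without replicate 19 at 100 mg/kg/d, and 69 without replicates 05 and 18.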

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

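Nothing in this part was weighed against an explanation. In the group of 5 libraries at 300 mg/kg/d, 123 measures were searched for a library far from the others, by the gap to its nearest neighbour over the whole range, with a limit of 0.71. Chance alone passes this limit in about 1 group in 20, or 6.15 of 123, and 9 measures passed it.

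Replicate 20 had a Leydig cell list score of -1.06, against -0.75 to -0.73 in the other libraries, with a gap over range of 0.915. Its Cyp11a1 level was 215 CPM against 287 to 304 CPM, with a gap over range of 0.814. Its share of ribosomal protein genes was 4.59% against 4.85% to 4.92%, with a gap over range of 0.793. Replicate 06 had 144 CPM of Mov10l1 against 179 to 190 CPM (0.766), 75.2 CPM of Mdm2 against 64.1 to 66.8 CPM (0.753) and a germ cell list score of 0.06 against 0.32 to 0.42 (0.731). Replicate 07 had 28.2 CPM of Sycp3 against 24.3 to 24.7 CPM (0.893) and an endothelial list score of -0.30 against -0.22 to -0.20 (0.763). Replicate 14 had 4.21 CPM of Synpo2l against 2.59 to 3.03 CPM (0.731).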

How the results depend on the processing

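The length correction and the fits without replicates 05 and 18 at 100 mg/kg/d were chosen after seeing the data. The cause of each shift below was not tested. Of the 49 called genes named at 300 mg/kg/d, 30 were called in every alternative, and at 100 mg/kg/d 8 of 38; no called gene changed sign. Among named genes not called, the sign differed in 130 of 2197 alternatives. In TPM the median of all genes moved by over 0.1 in 2 comparisons, to 0.14 and 0.17 from -0.01 for 300 against 100 mg/kg/d, and to -0.06 and -0.08 from 0.05 for 100 mg/kg/d against vehicle.

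Against vehicle, no low-count filter gave 1 call at 1 mg/kg/d, 19 at 11 mg/kg/d and, between the highest doses, 225. Fits of the compared groups alone gave 3, 10, 45 and 835 calls at 1, 11, 100 and 300 mg/kg/d and 0 between the highest doses. They took the dispersion from those groups alone, and why the counts at 1, 11 and 300 mg/kg/d rose was not tested. DESeq2 gave 24, 906 and 724 calls at 11, 100 and 300 mg/kg/d, 1244 between the highest doses and 282 shared calls. The sample code in the fit gave 1 call at 11 mg/kg/d, 270 at 300 mg/kg/d, 0 between the highest doses and 586 for the slope. Limma-voom gave 2 calls at 11 mg/kg/d. Log2(TPM + 1) gave 1 at 11 mg/kg/d and 246 at 300 mg/kg/d, and log2(TPM + 0.1) gave 181 at 100 mg/kg/d and 243 at 300 mg/kg/d. With the length trend removed 430 genes were called at 100 mg/kg/d. Subsets of 3 libraries at 300 mg/kg/d gave a median of 235.5 calls against vehicle (186 to 324) and 0 against 100 mg/kg/d. The slope on the dose itself gave 583.

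Leaving out each library in turn gave 0 calls in each fit at 1 mg/kg/d, 0 to 2 at 11 mg/kg/d (2 without vehicle replicate 08), 93 to 4250 at 100 mg/kg/d (without replicates 18 and 19) and 212 to 432 at 300 mg/kg/d (212 without vehicle replicate 15). It gave 0 to 5872 between the highest doses (0 without replicates 05, 14 and 20, 5872 without 19), 746 to 1503 for the slope and 70 to 301 shared calls (without vehicle replicate 01 and replicate 19).

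Without replicates 05 and 18 the counts were 73 at 100 mg/kg/d, 0 between the highest doses, 1711 for the slope and 69 shared. In that fit several lists turned direction. Immediate early genes at 100 mg/kg/d reached an adjusted p of 0.0277. Between the highest doses the adjusted p was 0.173 for cholesterol synthesis, 0.128 for endothelial markers, 0.00256 for mesonephric duct and epididymis markers, 0.650 for immediate early genes and 0.00960 for the cell cycle, and 6 lists were called.

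Over the 4 doses, camera called 46 list tests, 15 with an estimated correlation and 26 by fry. With an estimated correlation the calls were 0, 3, 4 and 8 at 1, 11, 100 and 300 mg/kg/d and 0 between the highest doses. Fry gave 0, 2, 12 and 12 at these doses and 3 between the highest doses. Of the lists that lost their call with an estimated correlation, fry left only red blood cells uncalled at 100 mg/kg/d (fry adjusted p = 0.205). At 300 mg/kg/d it left the myoid, endothelial, macrophage and immediate early lists uncalled (fry adjusted p of 0.105 to 0.156). Leaving out libraries gave 43 to 47 list calls over the doses, 5 to 8 at 1 mg/kg/d (5 without replicate 09), 8 to 10 at 11, 12 to 14 at 100, 14 to 16 at 300 mg/kg/d and 5 to 13 between the highest doses (5 without replicate 19). Depth limits genes of low level, such as Gsta2 at 300 mg/kg/d.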

Other observations

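The tests of gene length, of fewer Leydig cells, of dose and of the sample code for replicates 05 and 18, and of Cdh1 were chosen only after the result was seen. Several genes outside the lists went down over the doses, and they were picked here after their values were seen. Gsta2 had means of 16.7, 17.3, 4.12, 0.412 and 0.162 CPM in vehicle and at 1, 11, 100 and 300 mg/kg/d (slope -0.82, SE 0.0538, adjusted p = 1.67e-09). Olfm2, an olfactomedin protein, had 11.0, 10.3, 3.96, 1.49 and 1.35 CPM (slope -0.40, SE 0.0243, adjusted p = 8.28e-10). Lefty2 had 4.63, 4.17, 1.41, 0.912 and 0.559 CPM (slope -0.38, SE 0.0347, adjusted p = 3.10e-07), and Svs5 had 191, 110, 58.5, 44.4 and 10.4 CPM (slope -0.42, SE 0.0558, adjusted p = 4.23e-05). At 11 mg/kg/d against vehicle none of the 4 was called by edgeR, with adjusted p of 0.0789, 0.0604, 0.136 and 0.719.

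Alb, the gene of serum albumin, stood at 41.8 CPM in replicate 09 at 1 mg/kg/d and at 89.9 CPM in replicate 07 at 300 mg/kg/d, against at most 7.75 CPM in the other libraries. Afp had 25.7 and 34.7 CPM in these libraries and Fgb 6.27 and 11.9 CPM. Zp2 and H3f3c, like Cdh1, had separate levels within groups: the largest step between neighbouring libraries was from 0.845 to 21.5 CPM for Zp2 and from 8.44 to 45.9 CPM for H3f3c, each with libraries on both sides in 3 groups.

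Of 32 tested genes of Leydig cells and androgen synthesis 16 fell at 300 mg/kg/d, with a median log2 fold change of -1.37 (SD 0.591) over these 16, while the medians over all members were -0.77 for each list. The data argue against gene length bias and the sample code as the whole cause: the median was -1.36 with the length trend removed and -1.46 with the code in the fit, and 16 of 16 were still called in each. The 16 fell by different amounts (heterogeneity chi-square 188 with 15 degrees of freedom, and at least 137 without any 1 of them), so an equal loss of all 16 is excluded. Among Star, Cyp11a1, Hsd3b1, Cyp17a1, Insl3 and Lhcgr the chi-square was 31.5, and 6.73 without Hsd3b1, whose log2 level minus that of Cyp17a1 was 1.28 higher than in vehicle (SD 0.163 at 300 mg/kg/d and 0.137 in vehicle). Fewer Leydig cells with no change per cell cannot be told apart from lower expression per cell, because members that other cells also express would fall less, and their share in other cells was not measured.

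Replicates 05 and 18 at 100 mg/kg/d differed from the other 15 libraries in mitochondrial share and in a germ cell minus endothelial score. For the share, the data argue against a rise with dose, since the mean at 300 mg/kg/d was below vehicle (difference in percent -0.552, spread 0.422), while the lower of both replicates was 1.81 above it. They argue against the sample code as a whole, since the other 13 libraries with the same codes differed by -0.267 (spread 0.912) from the 2 of the remaining code. For the score, the data argue against gene length bias, since with the length trend removed the lower of both libraries stood at 1.10, above the 0.66 of the highest other library. Dose cannot be told apart as part of the score, because 5 of 5 libraries at 300 mg/kg/d, up to 0.63, lay above the highest vehicle library at 0.20. Dissection, RNA handling and differences between litters were not tested.

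Cdh1 was lower at 300 mg/kg/d than in vehicle. Dose of DPeP cannot be told apart as the cause: 5 of 9 libraries at 1, 11 and 100 mg/kg/d and 0 of 3 vehicle libraries were at or below the highest library at 300 mg/kg/d (14.5 CPM), so each low library was dosed, while replicate 19 at 100 mg/kg/d had 53.2 CPM. A strain variant that segregates among these outbred animals may give such levels. The largest ratio between neighbouring libraries was 3.65, with libraries on both sides in 3 groups. It cannot be told from counts, which carry no genotypes.

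Other splits of the same libraries were counted for each result. For 300 mg/kg/d against vehicle, 1 of 56 splits, the real one, called 432 genes or more, and the highest other called 1. This share is below 0.05 but the smallest that 56 splits allow. The same holds for the slope (1030 calls, 1 of 100 assignments, highest other 1). Other splits mix dosed and vehicle libraries within a group, which widens the spread there. Their low counts therefore do not show how many of the real calls are false. The 144 shared calls were reached by 1 of 100 assignments, with 0 as the highest other, which does not test sharing, as assignments that call few genes share none. For the lists between the highest doses 1 of 56 splits, the real one, gave as many as 12 at the preset correlation. That share is under 0.05, but it is the smallest these splits can give. As the highest other split gave 11, chance is not excluded for this count. With an estimated correlation 0 lists were called, with fry 3, and at the preset correlation without replicate 19 the count was 5. For the 16 lists at 300 mg/kg/d, 3 of 56 splits gave as many (highest other 16). The other splits with 16 grouped all vehicle libraries with replicates 06 and 13, or 07 and 13, against the remaining 300 mg/kg/d libraries. They carry part of the dose difference itself, so these splits cannot decide whether chance gives this count. Chance is not excluded for the 1 gene between the highest doses, as 7 of 56 splits gave as many. There the highest other split called 3882 genes. It grouped replicate 06 at 300 mg/kg/d with replicates 05 and 18, which points to a structure of the samples. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. At 1 mg/kg/d the real and highest other counts were 0 and 0 genes (10 splits as large) and 8 and 8 lists (2 splits), and at 11 mg/kg/d 0 and 0 genes (10 splits) and 9 and 7 lists (1 split). At 100 mg/kg/d they were 274 and 2453 genes (3 splits) and 13 and 10 lists (1 split), and the split with 2453 grouped vehicle replicate 15 with replicates 05 and 18, which also points to a structure of the samples.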
